A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

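The series holds 16 Saccharomyces cerevisiae chromatin immunoprecipitation libraries in 10 groups, and 22 peak lists were used here. The 4 G1 libraries come from cells arrested with the mating pheromone alpha-factor for 3 h at 23 degrees C, with 1 library each for an Mcm2 and an Mcm2-7 antibody in wild type (wt) and in mcm2DENQ. The 6 BrdU and 6 Mcm2-7 libraries in hydroxyurea (HU) come from cells released from that arrest into 0.2 M HU with BrdU at 400 µg/ml, with 2 replicates in each of wt, mcm2DENQ and mrc1∆. Per the labels' protocol the HU time was 90 min for replicate 1 of wt and 100 min for the other HU libraries analysed here. Samples were grouped by their titles. The labels do not say that the replicates were separate cultures, so the p-values over libraries measure only the spread between these samples, and those over sites or peaks describe the lists. The strains mcm2-1 and chaos3, which that protocol also mentions, were not analysed here.

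The deposited lists hold only a chromosome, a start and an end for each peak, with no height or score, and coordinates are 1-based in sacCer2, the build in the submitters' processing notes. Per the series' design text, the authors aligned reads with MAQ, kept those with a quality of 35 or more, and computed RPKM in overlapping bins. The bins were 5000 bp wide with a step of 1250 bp for BrdU, and 1000 bp wide with a step of 250 bp for Mcm, per the same design text. A bin was taken as enriched when it lay above a fixed quantile of its own chromosome's RPKM distribution, and overlapping enriched bins were merged, per that text. Replicates were quantile normalized and averaged per bin, and peak calls were intersected, per that text. The quantile was 0.95 for BrdU in wt, 0.75 for BrdU in both mutants and 0.96 in G1, per that text. The quantile for Mcm2-7 in HU, and the versions of the tools, are not given in the sources used here. Because the quantile was set per chromosome, the covered length of a list and its share on each chromosome follow largely from the quantile and are not free measurements. Comparisons of BrdU between wt and a mutant are therefore at unequal quantiles, and comparisons between the mutants are at equal ones. An equal quantile fixes the share of enriched bins, so wider peaks in a mutant leave less room for its weaker peaks. The RPKM values and the read depth behind the lists were not used here, so the depth is unknown and the confidence intervals below cover the number of sites or peaks only.

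Each replicate was listed separately, and each HU group also has a list that combines its 2 replicates. The combined BrdU lists were tested against the replicate lists and differed from their intersection in 0 bins of 250 bp in each strain. The combined Mcm2-7 lists differed from the intersection in 1176 to 1287 such bins. Peaks ending off the bin grid marked the ends of 6 chromosomes, and all 6 lengths equalled those of sacCer2. 1 peak that ran past a chromosome end was shortened to it.

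Lists were compared on a 250 bp grid. Peaks were taken as shared when they overlapped by at least 1 bp. A G1 site was a wt Mcm2-7 peak that overlapped a wt Mcm2 peak. Overlaps were tested by rotation, a permutation test in which 1 list was shifted by a random distance around each chromosome 10000 times, so that peak widths, spacing and chromosome shares were kept. The rotation test was one-sided for more overlap and two-sided for position relative to chromosome ends and centromeres, and its smallest possible p is 0.0001 (one-sided) or 0.0002 (two-sided). Strains were compared over the same sites with the exact McNemar test, and independent counts with Fisher's exact test, both two-sided. Values per library were compared with an exact permutation test, which with 2 libraries against 2 cannot give a p below 0.333. Shares carry Wilson 95% intervals, ratios of odds ratios carry bootstrap 95% intervals from 10000 draws of sites within each class, with 0.5 added to each count, and families of tests carry Benjamini-Hochberg adjusted p-values. The rotation test was tested on simulated lists of 400 peaks: 3 of 40 unrelated pairs had a p under 0.05, and 10 of 10 pairs had one when 10 percent of the peaks were made to coincide.

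Fixed before the data were examined were 9 early and 12 late or silent origins, 14 highly transcribed genes, the 16 centromeres and the ribosomal DNA. Their positions are textbook positions good to about 1 kb, and they were used with a window of 2 kb and are not printed. All 14 gene positions lay within 1 kb of the gene of that name in the R64 gene table, whose coordinates were not otherwise used. Individual peaks were named by a rule fixed at the same time: the 3 widest combined BrdU peaks per strain, the 3 widest per mutant that touched no wt peak, and the 3 widest G1 Mcm2-7 peaks per strain that were absent from the other. Apart from the listed genes, genes under these peaks are not named, because no annotation of sacCer2 was used. The alternatives were another overlap rule or window, stricter lists without peaks of 1 bin, each replicate left out, other definitions of a G1 site, lists without the ribosomal DNA and chromosome ends, a replicate block, and mutant BrdU lists limited to their widest peaks up to the covered length of wt. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.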

Results

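The libraries map where the Mcm2-7 complex, the core of the replicative helicase, sat on chromosomes in G1, and where DNA was synthesised and Mcm2-7 was found after release into HU. HU depletes nucleotides, and in wt cells the replication checkpoint then holds back late origins. mcm2DENQ carries a mutation in the ATPase site of the Mcm2 subunit, and mrc1∆ lacks Mrc1, a mediator of that checkpoint. BrdU, a thymidine analogue, marks newly made DNA. The design text states that the HU samples were made to assay late-firing origins. G1 groups had 1 library each and HU groups had 2.

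In G1, Mcm sites were largely shared by wt and mcm2DENQ. Of the 422 wt Mcm2-7 peaks, 345 (81.8%, Wilson 95% interval 77.8 to 85.1%) overlapped a mcm2DENQ Mcm2-7 peak, against 11.5% of peaks after rotation (permutation p = 0.0001, the smallest possible). Of the 377 mcm2DENQ peaks, 344 (91.2%, interval 88.0 to 93.7%) overlapped a wt peak. The Mcm2 antibody gave 338 of 436 wt peaks shared (77.5%) and 336 of 392 mcm2DENQ peaks shared (85.7%). Within a strain, the antibodies overlapped more: 93.1% of wt and 96.6% of mcm2DENQ Mcm2-7 peaks had a peak of the Mcm2 antibody. The mcm2DENQ lists held fewer peaks with either antibody, a difference of -45 for Mcm2-7, and covered 6.40% of the genome against 6.66% in wt. With 1 library per group, the difference in peak number has no replicate check.

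Of the G1 Mcm2-7 peaks, 77 in wt and 33 in mcm2DENQ had no counterpart in the other strain, and with the Mcm2 antibody 98 and 56. The widest wt Mcm2-7 peaks with no mcm2DENQ counterpart lay on chromosome XVI at 446001 to 448750, on XIII at 288001 to 290250 and on II at 719751 to 721750, with widths of 2.75, 2.25 and 2 kb. The widest mcm2DENQ peaks absent from wt lay on chromosome IV at 967001 to 970500, on V at 184501 to 187500 and on XIII at 192501 to 195250, with widths of 3.5, 3 and 2.75 kb. Of the 3 wt peaks, the one on chromosome II was a G1 site as defined here, that is, also found with the Mcm2 antibody in wt. The mcm2DENQ peaks could not be G1 sites by that definition, and the mcm2DENQ Mcm2 list was not checked for them.

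After release into HU, the mutants had more BrdU peaks than wt, and mrc1∆ had more and narrower peaks than mcm2DENQ. The lists held 139 ± 1.41 peaks in wt, 240.5 ± 9.19 in mcm2DENQ and 347 ± 14.1 in mrc1∆ (SD, n = 2 each). Mean peak width was 12.6 ± 0.103 kb in wt, 16.5 ± 0.478 kb in mcm2DENQ and 12.7 ± 0.378 kb in mrc1∆ (SD, n = 2). The peaks covered 14.6 ± 0.0293%, 33.0 ± 0.308% and 36.5 ± 0.40% of the genome in the same order (SD, n = 2). Each difference in peak number was larger than the spread between replicates, and the exact permutation p was 0.333 for each pair of strains, the smallest that 2 libraries against 2 allow. The mean width of mrc1∆ and wt peaks differed by 0.0482 kb, less than the spread (exact permutation p = 1). These means are at unequal quantiles and over different sets of peaks, so they do not show equal width at the same origins. The higher coverage in the mutants follows largely from their lower quantile. When the mutant lists were limited to their widest peaks up to the covered length of wt, peak number turned from higher to lower than in wt, by -83 in mcm2DENQ and -52.5 in mrc1∆, which follows by construction from keeping the widest peaks and says nothing about the quantile.

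The widest BrdU peaks held 2 to 4 G1 sites each. In wt they lay on chromosome XI at 438751 to 466250 around CEN11, on XIV at 538751 to 566250, both 27.5 kb wide, and on XVI at 545001 to 570000 around CEN16, 25 kb wide. In mcm2DENQ they lay on chromosome II at 226251 to 280000 around CEN2 (53.75 kb), on VII at 470001 to 518750 around CEN7 and PMA1 (48.75 kb), and on XIV at 536251 to 583750 (47.5 kb), the last over the wt peak on that chromosome. In mrc1∆ they lay on chromosome IV at 895001 to 927500 (32.5 kb), on XII at 132501 to 163750 around CEN12, and on XV at 328751 to 360000 (both 31.25 kb). At 69 wt peaks that held 1 G1 site and matched a peak with that 1 site in each mutant, the width was 11.3 ± 2.68 kb in wt, 18.0 ± 5.19 kb in mcm2DENQ and 13.8 ± 2.92 kb in mrc1∆ (SD over peaks). The mcm2DENQ peak was wider than the mrc1∆ peak at 55 of these origins and narrower at 7 (exact sign test p = 2.43e-10), a comparison chosen after the data were seen. At a fixed quantile, a list with fewer peaks must have wider ones, so width and number are not independent here.

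Most G1 sites had BrdU in mrc1∆, fewer in mcm2DENQ and a minority in wt, whose list was made at a stricter quantile. Of 393 G1 sites, 157 had a BrdU peak in wt (39.9%, Wilson 95% interval 35.2 to 44.9%), 291 in mcm2DENQ (74.0%, 69.5 to 78.1%) and 376 in mrc1∆ (95.7%, 93.2 to 97.3%). Single libraries gave 40.7 ± 0.720% in wt, 77.6 ± 2.88% in mcm2DENQ and 96.4 ± 0.720% in mrc1∆ (SD, n = 2). Sites that had BrdU in wt nearly all had it in the mutants: 3 sites had BrdU in wt and not in mcm2DENQ, and 0 in wt and not in mrc1∆. Conversely 89 sites had BrdU in mrc1∆ and not in mcm2DENQ, and 4 the reverse. The equal quantile of the mutants fixes the share of bins, so wider mcm2DENQ peaks can leave weaker sites out of its list.

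Each share exceeded that of rotated lists, by 2.49 times in wt, 2.19 times in mcm2DENQ and 2.42 times in mrc1∆ (permutation p = 0.0001, the smallest possible). The strains differed over sites by the exact McNemar test, with p = 6.56e-37 for mcm2DENQ against wt, 2.37e-66 for mrc1∆ against wt and 6.17e-22 for mrc1∆ against mcm2DENQ (adjusted 9.85e-37, 7.12e-66 and 6.17e-22 over 3 tests). Neighbouring sites are not independent, so these p-values describe the lists and not the spread between cultures. The contrasts with wt are also at unequal quantiles, 0.95 in wt and 0.75 in the mutants. Weak wt signal and a strain difference cannot be told apart in them. With the mutants limited to their widest peaks up to the wt covered length, the mcm2DENQ minus wt difference turned from 34.1 to -13.7 percentage points and the mrc1∆ minus wt difference from 55.7 to -3.31, a limit that drops narrow peaks by construction. With 5 kb around each BrdU midpoint the mcm2DENQ minus wt difference was 20.9 percentage points (exact McNemar p = 1.58e-11).

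**Figure D1:**
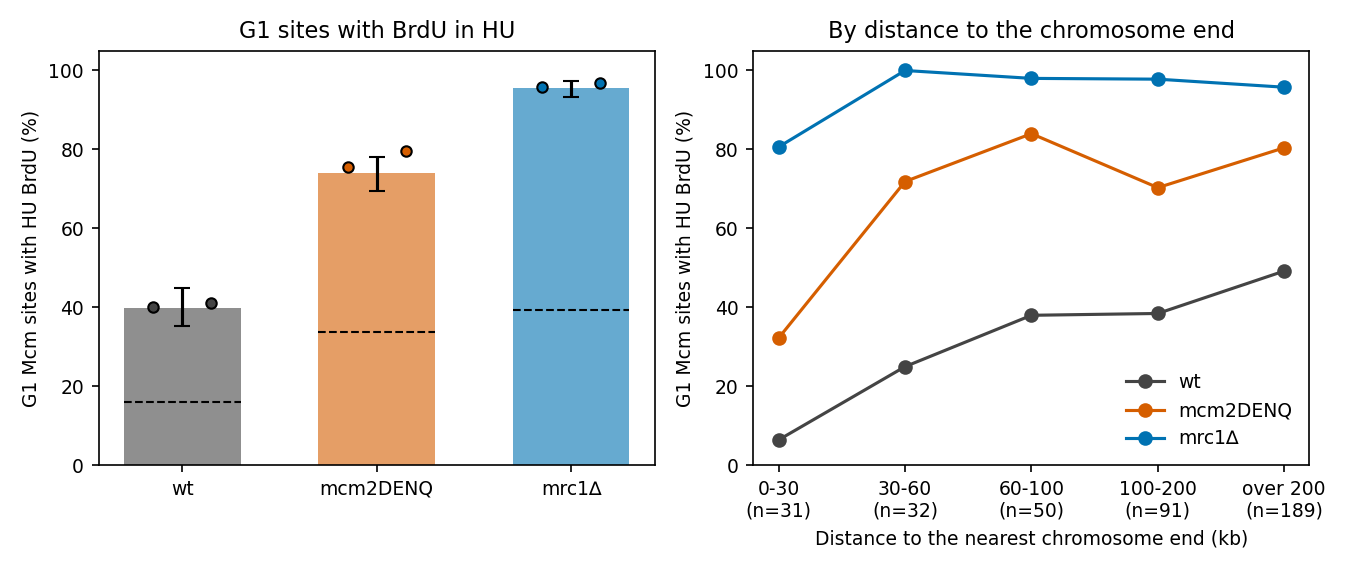
Left, share of the 393 G1 sites with an HU BrdU peak (%) in each strain: bars are combined lists with Wilson 95% intervals, points are replicate lists and dashed lines the mean of rotated lists. Right, the same share by distance to the nearest chromosome end (kb, number of sites under each class); within 30 kb it was 6.45% in wt, 32.3% in mcm2DENQ and 80.6% in mrc1∆.

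Early origins had BrdU in all 3 strains, and late origins had it throughout in mrc1∆ and rarely in wt and mcm2DENQ. Of the 9 listed early origins, 8 had BrdU in each strain and the exception was ARS305. Of the 12 listed late or silent origins, 1 had BrdU in wt (ARS605), 3 in mcm2DENQ (ARS604, ARS605 and ARS608) and 12 in mrc1∆, including those at the silent mating-type loci HML and HMR. Rotated lists gave 2.6, 4.38 and 5.64 late origins in the same order. Only mrc1∆ exceeded them (one-sided permutation p = 0.957, 0.878 and 4e-04 in that order). ARS604, which had no G1 Mcm2-7 peak, and ARS605 lay under the same BrdU peak in each mutant. HMR had no peak in any G1 list. A G1 site was found at 8 of the 12 late origins, and of these 8, 1 had BrdU in wt, 2 in mcm2DENQ and 8 in mrc1∆. The wt replicates gave 1 late origin each, the mcm2DENQ replicates 3 and 5, with ARS316 and ARS501 added in replicate 2, and the mrc1∆ replicates 12 each. At ARS501 the mrc1∆ peak ran from 545001 to 553750 on chromosome V, and at ARS603 from 65001 to 72500 on VI.

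Early and late origins differed in wt (Fisher's exact p = 3.71e-04, adjusted 0.00111 over 3 tests) and in mcm2DENQ (Fisher's exact p = 0.00752, adjusted 0.0113), and did not pass the test in mrc1∆ (Fisher's exact p = 0.429). Over the late origins, mrc1∆ differed from wt (11 against 0, exact McNemar p = 9.77e-04, adjusted 0.00293 over 3 tests) and from mcm2DENQ (9 against 0, exact p = 0.00391, adjusted 0.00586), and mcm2DENQ against wt gave 2 against 0 (exact p = 0.5). The wt list was at the 0.95 quantile and the mutant lists at 0.75, so contrasts with wt do not separate weak wt signal from a strain difference. Between the mutants, the fixed share of bins can leave weak late origins out of the mcm2DENQ list, whose peaks are wider. Over the late origins with a G1 site, a set chosen after the data were seen, mrc1∆ had 7 more than wt (exact McNemar p = 0.0156). It had 6 more than mcm2DENQ there (exact McNemar p = 0.03125). Counted once, ARS604 and ARS605 left 10 against 0 for mrc1∆ against wt (exact p = 0.00195) and 1 against 0 for mcm2DENQ against wt (exact p = 1), a count chosen after the data were seen. The early and late difference in mcm2DENQ rested on replicate 1: with replicate 2 alone it was 47.2 percentage points in place of 63.9 (Fisher's exact p = 0.0669). With the mutants limited to the wt covered length, the late origins no longer separated mrc1∆ from mcm2DENQ, with a difference of 0, or from wt, with 1 (exact McNemar p = 1 in both), and the early and late difference in mcm2DENQ was 27.8 percentage points (Fisher's exact p = 0.331). This limit drops narrow peaks, such as the mrc1∆ peaks at ARS501 and ARS603, by their width alone, so it does not show whether these origins fired.

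**Figure D2:**
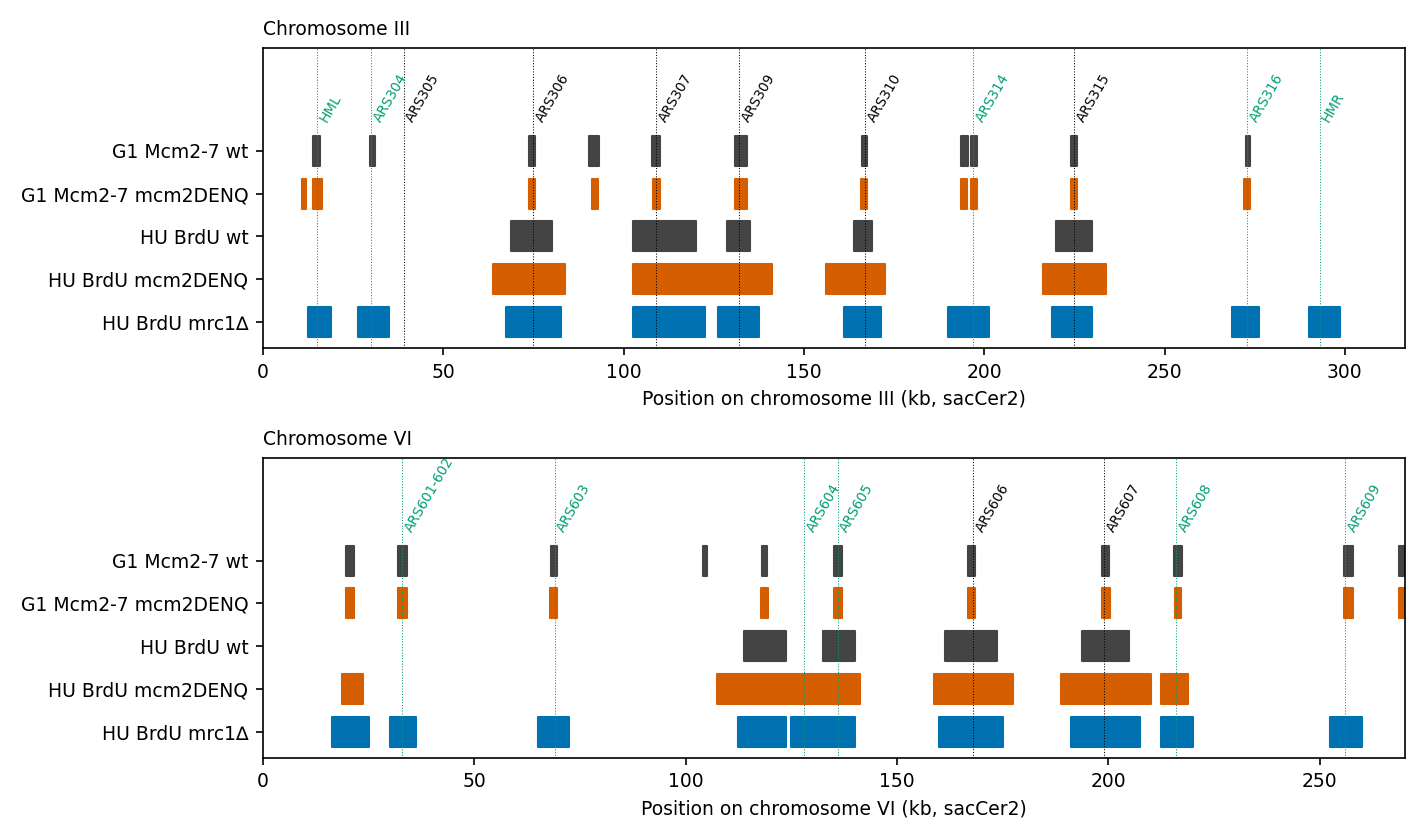
Peaks along chromosomes III and VI (kb, sacCer2), with G1 Mcm2-7 peaks and combined HU BrdU peaks by strain; origin names in black are early and in green late, drawn at textbook positions good to about 1 kb. On these chromosomes the late origins without wt BrdU lie under blue mrc1∆ peaks, and ARS305 lies under no peak.

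Most mcm2DENQ BrdU peaks that touched no wt peak had a counterpart in mrc1∆, which had others besides, and most in either mutant lay on G1 sites. These lists set mutant peaks at the 0.75 quantile against wt peaks at 0.95. Of 233 mcm2DENQ peaks, 113 touched no wt peak, and 109 of these (96.5%) touched a mrc1∆ peak that also touched no wt peak, against 37.5% after rotation (permutation p = 0.0001, the smallest possible). Of 208 such mrc1∆ peaks, 111 (53.4%) touched one of mcm2DENQ, against 20.9% after rotation (permutation p = 0.0001). Rotation left out the wt peaks but did not keep peaks on G1 sites. Of G1 sites without wt BrdU, 58.1% had BrdU in mcm2DENQ and 92.8% in mrc1∆. Most of this overlap can therefore come from the sites and the wt list that both share. A G1 site without wt BrdU was found in 109 of the mcm2DENQ peaks (96.5%, rotated 23.9%) and in 181 of the mrc1∆ peaks (87.0%, rotated 25%). The widest in mcm2DENQ lay on chromosome IV at 623751 to 645000 (21.25 kb), on VII at 650001 to 668750 (18.75 kb) and on IV at 1050001 to 1067500 (17.5 kb). The widest in mrc1∆ lay on VIII at 376251 to 397500, on XVI at 923751 to 945000 (both 21.25 kb) and on V at 273751 to 293750 (20 kb).

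Of the 236 G1 sites without wt BrdU, 137 had BrdU in mcm2DENQ (58.1%) and 219 in mrc1∆ (92.8%). Both had it at 133 sites, against 127 if the mutants were independent (Fisher's exact p = 0.00401). The mutant lists were used whole here, and only the sites were chosen by the wt list. Over all G1 sites, those within 30 kb of a chromosome end had BrdU less often in mcm2DENQ (32.3% against 77.6% elsewhere) and in mrc1∆ (80.6% against 97.0%). Part of this excess can come from such classes of sites, which was not tested.

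In HU, most Mcm2-7 peaks lay at G1 sites and in regions with BrdU. At a G1 site lay 194 of 252 wt peaks (77.0%, Wilson 95% interval 71.4 to 81.8%), 214 of 243 mcm2DENQ peaks (88.1%, 83.4 to 91.6%) and 309 of 382 mrc1∆ peaks (80.9%, 76.6 to 84.5%), against 13.3 to 15.8% after rotation (permutation p = 0.0001, the smallest possible). In a BrdU peak of the same strain lay 72.6% of wt, 91.8% of mcm2DENQ and 98.4% of mrc1∆ peaks, against 17.4%, 36.3% and 40.9% after rotation (permutation p = 0.0001). The share of G1 sites with HU Mcm2-7 rose from 41.5% in wt to 51.7% in mcm2DENQ and 67.4% in mrc1∆, with exact McNemar p = 6.42e-06 for mcm2DENQ against wt, 8.11e-12 for mrc1∆ against wt and 6.41e-06 for mrc1∆ against mcm2DENQ (adjusted 6.42e-06, 2.43e-11 and 6.42e-06 over 3 tests). The last difference fell from 15.8 to 4.83 percentage points when the site midpoint had to lie in the peak (exact McNemar p = 0.168), and the mcm2DENQ minus wt difference rose from 10.2 to 17.8 (p = 9.13e-13). With the peak midpoint at a G1 site, the wt excess of peaks over rotation was 31.1 in place of 61.4 percentage points, and with replicate 1 alone 39.2. The quantile of these lists is not known, and the combined mrc1∆ list covered more of the genome, 7.76% against 6.78% in wt and 6.70% in mcm2DENQ. Rotation gave 9.73% of G1 sites with HU Mcm2-7 in wt, 9.78% in mcm2DENQ and 12.25% in mrc1∆.

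Peak number was 268 ± 15.6 in wt, 269.5 ± 23.3 in mcm2DENQ and 402.5 ± 81.3 in mrc1∆, with mean widths of 3.10 ± 0.145, 3.09 ± 0.158 and 2.39 ± 0.326 kb (SD, n = 2). Coverage was 6.86 ± 0.0762%, 6.89 ± 0.245% and 7.86 ± 0.524% (SD, n = 2). wt and mcm2DENQ differed by less than the replicates did (exact permutation p = 1 for number, width and coverage), and the differences of mrc1∆ from each had exact permutation p = 0.333, the smallest possible. Mcm2-7 replicates matched less well than BrdU replicates: shared length was 42.3 to 48.6% of the joint length, against 86.5 to 94.1% for BrdU. The share of wt peaks at G1 sites was 54.1% in replicate 1 and 87.9% in replicate 2.

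Around active origins the HU Mcm2-7 peaks lay farther from the midpoint in wt than in mcm2DENQ. This comparison was chosen after the data were seen and used the 154 G1 sites with BrdU in all 3 strains. In the combined lists the midpoint was covered at 30.5% of sites in wt, 73.4% in mcm2DENQ and 33.1% in mrc1∆, and the positions 3 kb to each side at 52.9%, 33.1% and 7.79%. Replicates differed: midpoint and side positions were covered at 18.2% and 53.2% in wt replicate 1 and 51.3% and 51.6% in replicate 2, at 46.8% and 54.2% in mcm2DENQ replicate 1 (exact sign test p = 0.466) and 85.7% and 7.14% in replicate 2, and at 24% and 20.5% in mrc1∆ replicate 1 and 63.0% and 1.95% in replicate 2. Over the 116 sites with a value in both strains, covered positions within 6 kb lay 2.36 kb from the midpoint in wt and 1.84 kb in mcm2DENQ, and farther in wt at 94 sites and nearer at 19 (exact sign test p = 4.05e-13). The wt minus mrc1∆ difference of 0.392 kb did not pass the test in the combined lists (exact sign test p = 0.105), and with replicate 2 alone it was 0.732 kb (p = 8.47e-18). Replicate 1 lay farther out than replicate 2 in every strain, at 2.89 and 1.95 kb in wt, 2.29 and 1.4 kb in mcm2DENQ, and 2.36 and 1.14 kb in mrc1∆.

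**Figure D3:**
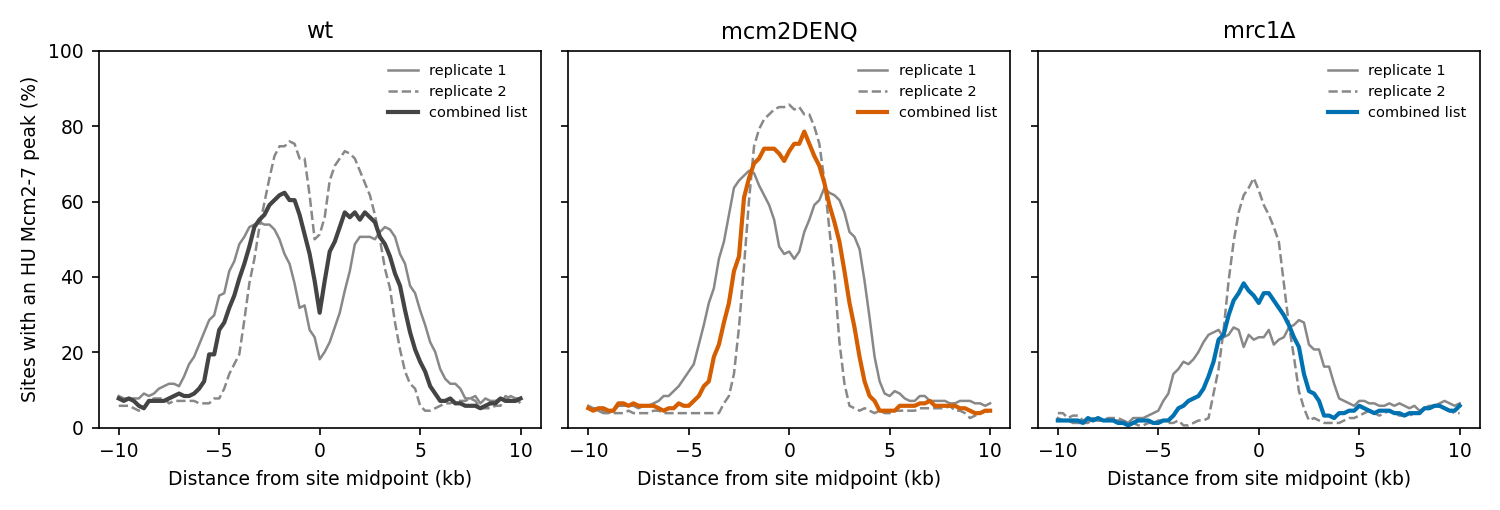
Share of the 154 G1 sites active in all 3 strains that were covered by an HU Mcm2-7 peak (%), by distance from the site midpoint (kb), in each strain; coloured lines are combined lists and grey lines replicates 1 (solid) and 2 (dashed). In wt coverage dips to 30.5% at the midpoint in the combined list, and in mcm2DENQ it is 73.4% there, with 46.8% in replicate 1 and 85.7% in replicate 2.

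In wt, BrdU and HU Mcm2-7 peaks were rare near chromosome ends and frequent near centromeres. Within 30 kb of a chromosome end lay 1.46% of wt BrdU peaks, 4.29% of mcm2DENQ and 6.76% of mrc1∆ BrdU peaks, where rotation gave 8.01 to 8.31%. G1 sites were not short of ends, at 7.89% against 8.04% after rotation (permutation p = 0.977). Within 15 kb of a centromere lay 21 of 137 wt BrdU peaks (15.3%), 3.70 times the rotated share, 15 of 233 in mcm2DENQ (6.44%) and 17 of 340 in mrc1∆ (5%), and G1 sites lay there at 6.62%, 1.64 times the rotated share (permutation p = 0.0012, adjusted 0.0044 over 22 tests). Of HU Mcm2-7 peaks, 14.7% lay near a centromere in wt, 9.88% in mcm2DENQ and 2.88% in mrc1∆ (permutation p = 0.0002, 0.0002 and 0.261), and 3.17%, 3.70% and 9.95% near an end (permutation p = 0.0058, 0.0050 and 0.140). Near centromeres the mcm2DENQ minus wt difference was -4.81 percentage points, and -0.342 with replicate 1 alone. The mrc1∆ minus wt difference there was -11.8 percentage points, and -7.81 with replicate 2 alone.

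The deficit of BrdU at ends had permutation p = 0.001 in wt and 0.0022 in mcm2DENQ (adjusted 0.0044 and 0.00691 over 22 tests) and 0.167 in mrc1∆, and the excess at centromeres p = 0.0002, the smallest possible, in wt and 0.0222 in mcm2DENQ (adjusted 0.00147 and 0.0376) and 0.269 in mrc1∆. Between strains, BrdU near ends differed for mrc1∆ against wt (Fisher's exact p = 0.0210, adjusted 0.0360 over 12 tests) and near centromeres for mcm2DENQ against wt (p = 0.00654, adjusted 0.0131) and mrc1∆ against wt (p = 5.33e-04, adjusted 0.00213). The lower centromere shares do not show a loss of BrdU there, since 134 and 137 of the 137 wt peaks had a peak in mcm2DENQ and mrc1∆, and peaks were added elsewhere at the lower quantile. HU Mcm2-7 peaks differed for mrc1∆ against wt near ends (Fisher's exact p = 9.53e-04, adjusted 0.00286) and centromeres (p = 5.63e-08, adjusted 6.75e-07), and for mrc1∆ against mcm2DENQ near ends (Fisher's exact p = 0.00461, adjusted 0.0111) and near centromeres (p = 2.91e-04, adjusted 0.00175), the latter falling from -7.0 to -4.06 percentage points with replicate 2 alone (p = 0.0608). Both mcm2DENQ calls rested on the combined list, since with replicate 2 or replicate 1 alone the permutation p was 0.183 and 0.0516 at ends and 0.282 and 0.0614 at centromeres. The mcm2DENQ minus wt difference near centromeres fell from -8.89 to -4.04 percentage points with a 10 kb window (Fisher's exact p = 0.125). The excess of mcm2DENQ HU Mcm2-7 peaks near centromeres was 5.77 percentage points over rotation, and 9.36 with replicate 1 alone.

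Over sites, BrdU near ends was rarer in each strain. Of the 31 G1 sites within 30 kb of an end, 2 had BrdU in wt (6.45%), 10 in mcm2DENQ (32.3%) and 25 in mrc1∆ (80.6%), against 42.8%, 77.6% and 97.0% of the 362 others (Fisher's exact p = 2.86e-05, 3.97e-07 and 9.86e-04, adjusted 4.29e-05, 1.19e-06 and 9.86e-04 over 3 tests). The mrc1∆ minus mcm2DENQ difference was 48.4 percentage points at end sites and 19.3 elsewhere, a gap of 29.1 (permutation p = 6.6e-04), a comparison chosen after the data were seen. mrc1∆ was near its ceiling elsewhere, and the odds ratios of mrc1∆ to mcm2DENQ, 8.03 at ends and 8.85 elsewhere, were not shown to differ (ratio 0.908, bootstrap 95% interval 0.283 to 3.75).

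Highly transcribed genes, where immunoprecipitates often show signal, were found more often than after rotation in the HU Mcm2-7 lists of wt and mcm2DENQ. Of the 14 listed genes, 7 lay within 2 kb of a peak in wt (permutation p = 7e-04, adjusted 0.00245 over 7 tests) and 8 in mcm2DENQ (permutation p = 3e-04, adjusted 0.0021), where rotation gave 1.83 and 1.97. In common were the glycolytic genes TDH3, ENO2, FBA1 and TPI1, PDC1 for pyruvate decarboxylase, PMA1 for the plasma membrane proton pump, and CCW12 for a cell wall protein, and mcm2DENQ added CDC19 for pyruvate kinase. mrc1∆ had 3, TDH3, CDC19 and FBA1 (permutation p = 0.483), and each G1 list had 4, CDC19, FBA1, TPI1 and PDC1 (permutation p = 0.237 to 0.312). Of HU Mcm2-7 peaks off G1 sites, 2 in wt, 1 in mcm2DENQ and 3 in mrc1∆ lay within 2 kb of a listed gene. Signal at these genes was therefore not separated from Mcm2-7 at G1 sites. The mcm2DENQ and mrc1∆ counts differed at 5 genes against 0 (exact McNemar p = 0.0625). With a 5 kb window the G1 Mcm2-7 lists also passed, with permutation p = 0.012 in wt and 0.0038 in mcm2DENQ.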

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

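Of the tests below, those on end sites, on odds ratios, on sites absent from the mcm2DENQ G1 lists, on widths at single origins and on wt replicate 2 over all G1 sites and over late origins in mrc1∆, and on shifts within mcm2DENQ peaks were chosen only after the result was seen. The results listed here are those in which the effects of mcm2DENQ and mrc1∆, listed at equal BrdU quantiles, differed from each other. Equal quantiles fix the share of enriched bins, so the wider mcm2DENQ peaks leave less room for weaker ones. How far this lowered its counts of sites and late origins with BrdU was not tested. The share of G1 sites with BrdU was 21.6 percentage points higher in mrc1∆ (exact McNemar p = 6.17e-22), and 9 listed late origins had BrdU in mrc1∆ and not in mcm2DENQ (exact McNemar p = 0.00391). With both lists limited to the wt covered length, these differences were 10.4 percentage points (exact McNemar p = 2.03e-05) and 0 origins. That limit drops narrow peaks by construction. G1 sites with HU Mcm2-7 made up 67.4% in mrc1∆ against 51.7% in mcm2DENQ (exact McNemar p = 6.41e-06). The quantile of the HU Mcm2-7 lists is not known, so these may not be at equal quantiles. Of HU Mcm2-7 peaks, 9.95% lay near a chromosome end in mrc1∆ against 3.70% (Fisher's exact p = 0.00461), and 2.88% near a centromere against 9.88% (Fisher's exact p = 2.91e-04, and 0.0608 with replicate 2 alone). The gap between the mutants was 29.1 percentage points wider at end sites than elsewhere (permutation p = 6.6e-04). It was 27.7 percentage points wider at sites absent from the mcm2DENQ G1 lists than at other sites (permutation p = 3e-05). mrc1∆ was near its ceiling at the other sites in both comparisons, and as ratios of odds ratios neither gap was shown, at 0.908 for ends (bootstrap 95% interval 0.283 to 3.75) and 1.29 for absent sites (0.452 to 4.35). BrdU peaks at single origins were 4.20 kb wider in mcm2DENQ (exact sign test p = 2.43e-10).

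The first pattern is that the mutants had more BrdU peaks, and more late origins with BrdU, than wt. Background bins let in by the lower quantile could add peaks, but mutant peaks without a wt counterpart lay on G1 sites without wt BrdU far more often than rotated ones (larger permutation p of the mutants 0.0001, the smallest possible). The shorter HU time of wt replicate 1 does not account for the difference over all sites, since mcm2DENQ exceeded wt by 38.4 percentage points in replicate 2, where the times were equal, nor for the late origins in mrc1∆, where replicate 2 had 12 against 1 in wt (exact McNemar p = 9.77e-04) and wt replicate 1 also had 1. For the late origins in mcm2DENQ, the equal counts of the wt replicates give it no sign either, but with 2 fewer in wt replicate 2 than in the combined mcm2DENQ list, and 4 fewer than in mcm2DENQ replicate 2 (exact McNemar p = 0.125), the origins are too few to exclude it. Weak wt signal under the stricter wt quantile and a strain difference cannot be told apart, since 0 wt lists at the mutants' quantile were analysed here.

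The second pattern is that mrc1∆ had more and narrower BrdU peaks than mcm2DENQ at the same quantile. The breaking of mcm2DENQ peaks by noise was not the whole cause, since 91 mrc1∆ peaks touched no mcm2DENQ peak, and 72 of these held a G1 site (79.1%, rotated 32.2%, permutation p = 0.0001, the smallest possible). Whether noise broke 19 mcm2DENQ peaks into 39 mrc1∆ peaks stays open: 33 of the 39 held a G1 site (84.6%), more than the 43.6% of genome-wide rotation (permutation p = 0.0001), but shifting them around the mcm2DENQ peak they shared gave 79.1% (permutation p = 0.179). The test on replicate-specific peaks was moved to peaks of either replicate, because the combined list is their intersection by construction, and of 110 such peaks outside mcm2DENQ peaks, 80% were in both replicates (Wilson 95% interval 71.6 to 86.4%), against 99.6% of 244 inside them. The bound set beforehand was 80%, which the share meets exactly and its interval spans, and that the interval should clear the bound was required only after the value was seen, so this stays open beside a difference between the strains themselves.

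The third pattern is the set of HU Mcm2-7 peaks that touched no G1 site, 58 in wt, 29 in mcm2DENQ and 73 in mrc1∆. They lay within 10 kb of a G1 site with BrdU in the same strain more often than rotated lists (largest permutation p of the strains 3e-04), as positions flanking active origins would. As 74.0% of G1 sites in mcm2DENQ and 95.7% in mrc1∆ had BrdU, nearness to any G1 site would give much the same there. A comparison with G1 sites without BrdU was not made. Signal at highly transcribed genes could add to them and stays open, since the listed genes lay near HU Mcm2-7 peaks more often than after rotation in wt and mcm2DENQ, and in mrc1∆ the permutation p was 0.483 with 3 genes. Of the peaks that touched no G1 site, 2, 1 and 3 lay within 2 kb of a listed gene in wt, mcm2DENQ and mrc1∆. A spread of Mcm2-7 with moving forks is a biological candidate explanation that was found and tested on the same lists. In the form tested below, at 3 kb to each side, it held in wt replicate 1 (82 sites against 22) but not in replicate 2 (31 against 31). It was thus not borne out in that form, which cannot show a smaller shift. In wt replicate 2 the midpoint was covered at 51.3% of sites and the positions 1.5 kb to each side at 76.0% and 72.7%, looked up afterwards. A smaller shift therefore stays open.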

How the results depend on the processing

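The alternatives for Mcm2-7 distance, single-origin width, end sites, sites absent from the mcm2DENQ G1 lists, origins with a G1 site and ARS604 with ARS605 counted once were chosen only after the result was seen. Of 402 alternatives to 79 results, 344 left direction and call as they were, of which 43 moved the value over 1.5 times. Some of the 344 could not change. For peak number, mean width and coverage a replicate block gives the main value by construction, and the intersection of replicates is the combined BrdU list itself. Another 24 reversed the direction, 13 lost a call, 9 gained a call, and 12 moved a value without a test over 1.5 times or an uncalled one to 0. The cause was not tested except where named. Limiting the mutants to the wt length keeps their widest peaks by construction, so it drops narrow peaks whatever the quantile. It gave -83 (mcm2DENQ) and -52.5 (mrc1∆) BrdU peaks minus wt, mean widths 18.5 and 7.68 kb above wt and covered shares -0.109 and -0.0104 points from wt. G1 sites with BrdU were then -13.7 (p = 5.15e-09) and -3.31 points (p = 0.241), late origins 1 more in mrc1∆ than in wt and 0 more than in mcm2DENQ (exact p = 1), and early minus late origins 27.8 points in both mutants (p = 0.331). Each replicate left out gave these ranges: BrdU width, mrc1∆ minus wt, -0.146 to 0.243 kb; HU Mcm2-7 peaks, mcm2DENQ minus wt, -4 to 7 in number, -0.0124 to 0.00511 kb in width and -0.0953 to 0.144 points in coverage, and in number, mrc1∆ minus wt, 88 to 181. Early minus late origins in mcm2DENQ were 47.2 (exact p = 0.0669) to 63.9 points. Against rotation, mcm2DENQ BrdU lay -2.42 to -1.66 points at ends (permutation p = 0.0516 and 0.183) and 1.18 to 1.97 at centromeres (p = 0.282 and 0.0614). Likewise mrc1∆ BrdU lay -1.0 to 0.828 points at ends and mrc1∆ HU Mcm2-7 -0.530 to 0.572 at centromeres. BrdU at ends, mcm2DENQ minus wt, was 4.11 to 5.05 points (exact p = 0.0237 without replicate 1), and HU Mcm2-7 at centromeres, mrc1∆ minus mcm2DENQ, -10.2 to -4.06 (exact p = 0.0608 without replicate 1). HU Mcm2-7 distance was 0.178 to 0.732 kb for wt minus mrc1∆ (exact p = 8.47e-18 without replicate 1) and, without replicate 1 and 2 in turn, 0.289 (p = 3.68e-07) and -0.157 kb (p = 0.163) for mcm2DENQ minus mrc1∆, and -0.326 kb with a 10 kb reach (p = 0.921). The combined lists gave a BrdU width of -0.0979 kb (mrc1∆ minus wt) and, for HU Mcm2-7 in mcm2DENQ minus wt, -9 peaks, 0.0801 kb and -0.0808 points. Without peaks of 1 bin these were 0.0249 kb, -6.5 peaks, 0.0670 kb and -0.0383 points. Without ribosomal DNA and ends the BrdU width was 0.270 kb (mrc1∆ minus wt), and coverage 2.03 points (mrc1∆ minus mcm2DENQ). Early minus late origins in mrc1∆ were 0 with a 5 kb window and with the origins that have a G1 site. Transcribed genes in G1 Mcm2-7 were 33.5 (wt, permutation p = 0.012) and 37.0 points (mcm2DENQ, p = 0.0038) above rotation at 5 kb. At other distances, G1 sites were 0.602 points above rotation at ends (50 kb) and 1.37 at centromeres (10 kb, permutation p = 0.0676). mrc1∆ BrdU at centromeres was 1.76 (25 kb, permutation p = 0.0426), mrc1∆ HU Mcm2-7 4.42 at ends (50 kb, p = 0.0036) and -1.65 at centromeres (10 kb, p = 0.0426). mcm2DENQ minus wt was 5.79 (BrdU, ends, 50 kb, exact p = 0.0400), -4.04 (BrdU, centromeres, 10 kb, p = 0.125) and -0.382 points (HU Mcm2-7, ends, 20 kb). With the site midpoint required, G1 sites with HU Mcm2-7 were 4.83 points (mrc1∆ minus mcm2DENQ, exact p = 0.168). As a hint only, since no label says that replicate numbers share a batch, a replicate block gave 55.6 points for early minus late origins in mcm2DENQ (p = 0.0669), and deviations of same-numbered libraries correlated at -8.73e-05 to 0.0378 for BrdU and 0.15 to 0.295 for Mcm2-7. Depth is unknown from the lists, so how far weak peaks were missed in any strain was not analysed here.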

Other observations

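The tests on absent sites, end sites, odds ratios and Mcm2-7 position in this part were chosen only after the result was seen. Of the 393 G1 sites, 55 overlapped no peak of either mcm2DENQ G1 list. These sites had BrdU in mcm2DENQ at 43.6%, against 79.0% of the 338 others (Fisher's exact p = 2.07e-07, adjusted 6.22e-07 over 3 tests). In wt the shares were 29.1% and 41.7% (Fisher's exact p = 0.102), and in mrc1∆ 89.1% and 96.7% (Fisher's exact p = 0.0207, adjusted 0.0310). Of the 55 sites, 3 lay within 30 kb of a chromosome end.

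ARS305, an early origin in textbook accounts, was the 1 listed origin with no peak within 2 kb in any of the 22 lists, the G1 lists included, and the cause was not tested. ARS609, a late origin near the right end of chromosome VI, had an HU Mcm2-7 peak in both replicates of wt, mcm2DENQ and mrc1∆ but BrdU in mrc1∆ only. Both origins were singled out after their values were seen.

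One hypothesis was that Mcm2-7 moved away from active origins with the forks in HU, in which case wt positions 3 kb to each side would be covered more often than the midpoint in both replicates. Replicate 1 showed this at 82 sites against 22 (exact sign test p = 2.57e-09), but replicate 2, with the longer HU time, had 31 against 31 (p = 1), so the hypothesis in this form was not borne out. In replicate 2 of wt the midpoint was covered at 51.3% of sites and the positions 1.5 kb to each side at 76.0% and 72.7%, values that were looked up afterwards. The test at 3 kb could not show a shift of that size, so a smaller shift stays open. A difference between replicate numbers shared by all strains is a candidate explanation for part of the pattern. Replicate 1 lay farther out in every strain, by up to 1.22 kb (in mrc1∆), more than the smaller wt minus mcm2DENQ difference within a replicate number of 0.488 kb, and the order of mcm2DENQ and mrc1∆ changed between replicate numbers. wt lay farther out than mcm2DENQ within both numbers.

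Another hypothesis was that origins near chromosome ends stay silent in mcm2DENQ in HU but not in mrc1∆. The gap between the mutants in percentage points was wider at ends (permutation p = 6.6e-04), but nearly all other sites had BrdU in mrc1∆, which limits the gap there. As odds ratios, which this ceiling does not limit, the gap at ends (8.03) was not shown to differ from that elsewhere (8.85), so the hypothesis stays open.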
